A study of Mus musculus with 48 samples.

How the data were processed

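The series holds 48 mouse cerebellum samples: 20 chromatin immunoprecipitation samples at postnatal day 22, 16 messenger RNA samples at days 27 to 28 and 12 Sync-TRAP samples at day 12. The chromatin samples and the 3 input cKO Sync-TRAP samples have no values per sample in the files used and were not analysed here. The files used were 4 tables of genes and 2 lists of regions.

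Each gene table gives log2 CPM per library, made by the authors with a prior count, and the authors' comparison of 2 groups: a log2 fold change, a mean log2 abundance, a likelihood ratio, a p-value and an adjusted p-value, per the file headers. The deposited values per library share a floor, the value of 0 reads. Reads were aligned with Bowtie to build mm9 and compared with edgeR, per the submitters' processing notes, which also name SICER and bedtools. Versions, the counting tool and the filters are not given in the sources used here. The deposited p-values and adjusted p-values show that each table lists only genes with an adjusted p under 0.05, and adjusted p times rank over p gave about 27100, 26900, 25800 and 26200 features tested. The deposited tables repeat a gene once for each of its Entrez identifiers. Repeated lines, 49 in the cKO table and 5 in the rotarod table, were removed, so that each gene counts once (5557 and 913 lines became 5508 and 908 genes). The ratio that gives the features tested is steadier over ranks without them. Identifiers matched the reference gene names for 5482 of 5508, 902 of 908, 38 of 38 and 51 of 51 genes. The region lists hold chromosome, start and end on build mm9, and the reference annotation is of another build, so regions were not joined to genes.

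After the floor was removed, low values of a library were whole multiples of the value of 1 read. All (100%) of the values of up to about 20 reads lay within 0.1 read of a whole number in the cKO, rotarod and IP libraries, which gave effective library sizes of 13.7 to 15.6, 13.7 to 16.7 and 23.0 to 27.1 M reads. Only 5 to 10 low values per library supported the IP sizes. Input depth was not recoverable. Intervals and floors cover counting error only. Replicates are separate samples in the labels, so the p-values of limma and of the authors' test measure the spread between these samples.

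The design fixed before the data were examined foresaw counts or normalized values of all genes. The tables hold log2 values of called genes, so count models were not run. Counts of changed genes are the authors' deposited calls. Differences and errors come from limma 3.58.1 (R 4.3.3) on the deposited log2 values of the listed genes, with no added pseudocount and Benjamini-Hochberg adjustment over the features tested. Its variance prior was estimated from called genes alone, and genes absent from the tables count as not called. Tested on simulated data with 200 changed genes, this fit recovered 63.0% and 86.0% of log2 changes of 0.5 and 1 among 5508 genes with the spread of the cKO table, and 78.0% and 92.0% among 908 genes with that of the rotarod table. False genes made up 3.87% and 5.03% of the calls. In these simulations the adjustment ran over the simulated genes alone.

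Enrichment of gene lists among all genes, adjustment over a list alone, rotation or correlation-adjusted set tests and random sets matched on abundance all need genes that were not called, and were not run. Instead, Fisher's exact test (two-sided, scipy 1.17.1) compared the higher and lower counts of a list's members with those of the other listed genes, Benjamini-Hochberg adjusted over the lists with a listed member. It takes genes as independent, so its p does not measure the spread between samples. The fixed design foresaw counts alone, and no Fisher test, for tables of selected genes, so this test departs from it and was chosen after the data were seen. The 25 lists, with 463 genes, were written before. Regions were compared with bedtools 2.31.1 at 1 bp of overlap.

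Named genes follow a rule fixed before: Chd4, the 12 genes with the largest and the 12 with the smallest log2 fold changes among called genes at or above the median abundance, leaving out predicted genes, and up to 4 members of each list. The Sync-TRAP tables had no abundance limit. Pull-down and input libraries of WT carry the same title numbers (CB1 to CB3) and were taken as paired, because a pull-down is made from its input. The sources used here do not state it, and this reading was adopted after the blocked counts were seen. The deviations of the pairs from their group means correlated at 0.394, -6.4e-04 and 0.344. The columns of the rotarod table carry numbers that match no sample title, so those libraries are known by group alone and are called by column number. Alternatives tried were stricter thresholds, minimum folds, abundance limits, other adjustments, limma with a trend, pseudocounts of 0.1, 1 and 5 CPM, subsets of libraries, a replicate block and each library left out.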

Results

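The samples were mouse cerebella, either wild type (WT) or with a conditional knockout of Chd4 (cKO). Chd4 is the ATPase of the NuRD nucleosome remodeling complex. Messenger RNA at postnatal days 27 to 28 was sequenced from 4 WT and 4 cKO cerebella, and from 4 cerebella of mice trained on a rotarod (a rotating rod on which a mouse must keep its balance) and 4 of mice left at rest. Ribosome-bound RNA was sequenced at postnatal day 12 by Sync-TRAP, a pull-down of tagged ribosomes, with 3 pull-down (IP) and 3 input libraries of each genotype. The effective depth read from the values was 13.7 to 15.6 M reads per library for cKO and WT, 13.7 to 16.7 M for rotarod and rest, and 23.0 to 27.1 M for the IP libraries. The tables hold only genes with an adjusted p under 0.05 in the authors' test, so a gene they do not list has no value here. A gene is said to have risen or fallen where it passed that test. Levels are log2 CPM, read counts scaled to the size of the library. Differences are in log2 CPM ± SE from limma, with limma's own adjusted p beside some of them.

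The cKO was compared with WT to ask which genes depend on this remodeler in the cerebellum. Chd4 itself fell by 0.44 ± 0.06 on the log2 scale, to 0.739 of its WT level (limma adjusted p = 0.00199, n = 4 per genotype). The value covers the gene as a whole in the cerebellum, and does not show which parts of the transcript remained or in which cells. WT libraries 1 to 4 held 8.34, 8.45, 8.41 and 8.31 log2 CPM of Chd4, and cKO libraries 1 to 4 held 8.06, 7.90, 7.90 and 7.90. The authors' deposited table lists 5508 genes, 2990 higher and 2518 lower in cKO, out of about 27100 features tested. Of these, 868 rose and 170 fell by at least 2-fold (an absolute log2 fold change of 1 or more in the authors' deposited table). The highest rise among the abundant genes was that of Nhlh1, a helix-loop-helix factor of newborn neurons, with 9 reads over the 4 WT libraries and 4405 over the 4 cKO libraries. Its log2 difference was 8.10 ± 0.24 (limma adjusted p = 1.15e-06).

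Hmcn2, which encodes an extracellular hemicentin, rose by 6.95 ± 0.33 (limma adjusted p = 9.68e-06). Elavl2, a neuronal RNA-binding protein gene, rose 9.48-fold, from 4.85 ± 0.11 to 8.09 ± 0.13 log2 CPM (SD, n = 4). The kinase gene Mapkapk3 rose 7.77-fold, the copine gene Cpne6 7.56-fold and the G-protein subunit gene Gng4 7.46-fold. The noncoding RNA Miat rose 6.81-fold, the laminin gene Lama5 5.52-fold, Smoc1 5.07-fold, the nociceptin receptor gene Oprl1 4.44-fold, Vwa5b2 4.43-fold and the anchoring protein gene Akap5 4.36-fold. Limma's adjusted p was at most 1.9e-05 for these genes and Nhlh1.

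The genes that fell most among the abundant ones changed less. Bcl2l15, a Bcl2 family gene, was 3.26-fold lower, the collagen gene Col27a1 3.26-fold, Crtam 3.17-fold, the phosphatase gene Ptpn22 3.14-fold and the cytokine receptor gene Il20rb 2.82-fold. Svep1 was 2.50-fold lower, Rnf112 2.43-fold, Inadl 2.33-fold, Cgnl1 2.28-fold, Tbata 2.26-fold and Mctp1 2.23-fold. Limma's adjusted p was at most 0.00101 for these genes.

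**Figure D1:**
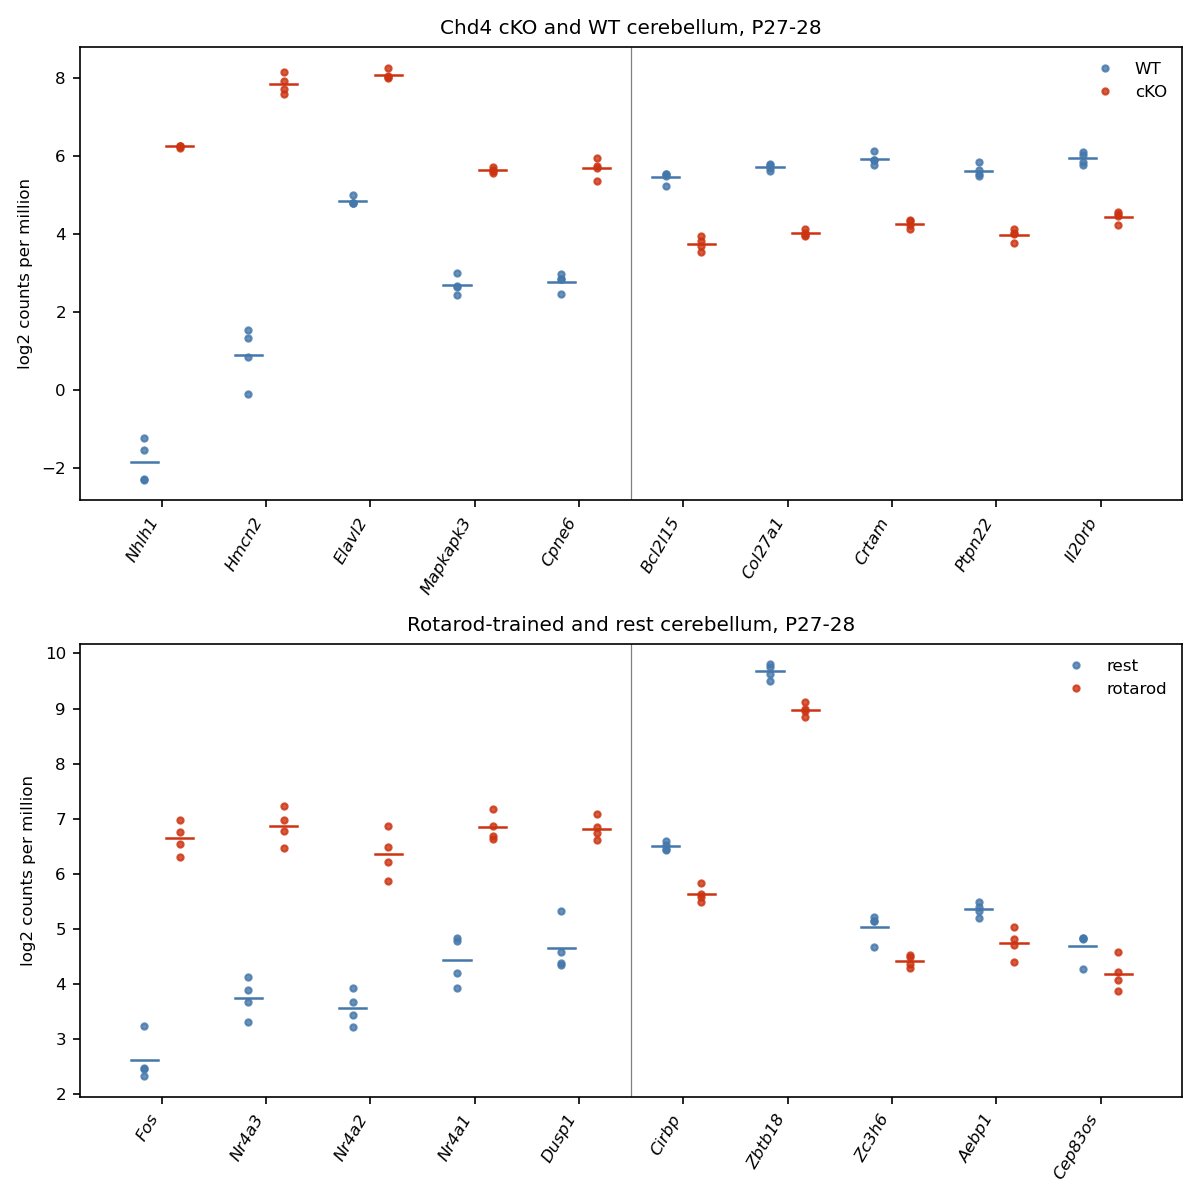
Log2 CPM of each library for the 5 genes with the highest and the 5 with the lowest log2 fold changes in the cKO (upper panel) and rotarod (lower panel) comparisons, among abundant genes. Points are libraries, bars are group means of 4 libraries, and the vertical line parts the genes that rose from those that fell.

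Of 15 genes in the NuRD list, which includes Chd4, 5 rose, 2 fell and 8 are not listed, and their direction did not pass the test (Fisher's exact test against the other listed genes, adjusted p = 0.716). The paralogous ATPase genes Chd5 and Chd3 rose 3.25-fold and 1.73-fold (log2 differences 1.70 ± 0.10 and 0.79 ± 0.05). Gatad2a rose by 0.55 ± 0.07, and Cdk2ap1 fell by 0.82 ± 0.11.

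Activity-regulated genes, which neurons switch on with firing, moved both ways. Of 24 activity-regulated transcription factor genes, 9 rose and 5 fell in cKO. Atf3 rose by 1.40 ± 0.21 and Cebpb by 0.90 ± 0.12, and Egr4 fell by 0.64 ± 0.13. Fos rose by 1.11 ± 0.36, which did not pass limma (adjusted p = 0.0875). Fos also differed by 0.94 log2 between the libraries numbered 1 and 2 and those numbered 3 and 4, across both genotypes. Within libraries 1 and 2 the cKO minus WT difference of Fos was 0.83 ± 0.12, and within libraries 3 and 4 it was 1.39 ± 0.14. With the library number as a block limma passed Fos (adjusted p = 0.0136), although the numbers were taken as not pairing the libraries. Of 33 activity-regulated effector genes, 9 rose and 5 fell. Arc, a cytoskeletal gene of dendritic spines, rose 2.76-fold, the secretogranin gene Scg2 1.76-fold and the phosphatase gene Dusp1 1.70-fold, while Dusp4 fell by 0.71 ± 0.07. Limma passed 4 higher and 2 lower transcription factor genes, and 8 higher and 3 lower effector genes. For neither list did the direction pass a test against the other listed genes (Fisher's exact test, adjusted p = 0.716 for both).

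Listed markers of cell types other than granule neurons were mostly lower. Over 9 lists with 130 markers, 57 of the 60 listed markers were lower in cKO and 3 were higher, and 70 are not listed. The listed ones had a median log2 difference of -0.28. For Purkinje cells, 11 of 15 genes fell and none rose (Fisher's exact test against the other listed genes, adjusted p = 0.0045). Genes of a list come from the same libraries and are not independent replicates. Pcp2 fell by 0.37 ± 0.06, Rgs8 by 0.26 ± 0.05 and Itpr1 by 0.25 ± 0.05. Of 18 oligodendrocyte genes 10 fell, among them Pdgfra by 0.39 ± 0.08, Olig1 by 0.36 ± 0.08, Fa2h by 0.35 ± 0.12 and Olig2 by 0.34 ± 0.11 (Fisher's exact test, adjusted p = 0.00494). Of 17 vascular genes 9 fell, with Cdh5 down by 0.46 ± 0.10, Tek by 0.43 ± 0.11, Flt1 by 0.39 ± 0.11 and Acta2 by 0.38 ± 0.08, and of 13 meningeal and fibroblast genes 9 fell (Fisher's exact test, adjusted p = 0.00541 for each list). Among genes at or above the median abundance, where 11 Purkinje, 8 oligodendrocyte, 6 meningeal and 2 vascular genes fell and none rose, the unadjusted Fisher's exact p of these lists was 0.001, 0.00793, 0.0315 and 0.5. The meningeal genes Igf2, Fmod, Slc6a13 and Mgp differed by -0.38, -0.37, -0.34 and -0.32, and none passed limma. Of all listed genes that fell, limma passed 6 of 11 Purkinje, 2 of 10 oligodendrocyte, 6 of 9 vascular and 0 of 9 meningeal genes.

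Of 14 inhibitory interneuron genes 8 fell, including Slc6a5 by 0.45 ± 0.12, Grm2 by 0.42 ± 0.09 and Slc32a1 by 0.37 ± 0.10, and Prkcd rose by 0.41 ± 0.06. Of 16 astrocyte and Bergmann glia genes 5 fell, including Sox9, Gja1, Aldoc and Slc4a4, by 0.22 to 0.41. These 2 lists had Fisher's exact adjusted p of 0.0711 and 0.083. Limma passed 6 of the 8 interneuron genes and 3 of the 5 astrocyte and Bergmann glia genes that fell. The microglia gene Ctss was 0.41 ± 0.14 higher, the only one of 14 listed. Among choroid plexus genes Folr1, Calml4 and Otx2 had log2 differences of -1.24, -1.01 and -0.42, none past limma, and libraries of one genotype differed in Folr1 and Calml4 by as much (SD 1.29 and 1.28 in cKO). Of 9 red blood cell genes, Slc4a1 rose by 1.01 ± 0.11 and Hba-a1 differed by -0.45 ± 0.32.

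Granule neuron genes were divided. Of 22 mature granule neuron genes, 6 rose and 7 fell: Calb2 rose by 0.96 ± 0.07 and Pax6 by 0.45 ± 0.05, while Cbln3 fell by 0.58 ± 0.05 and Zic2 by 0.50 ± 0.06. Of 20 genes of early neuronal differentiation, 7 rose and 3 fell. Robo3 rose by 1.14 ± 0.20 and Draxin by 0.89 ± 0.13, and Igfbpl1 differed by -0.95 ± 0.39, with 4 reads in cKO and 16 in WT. Of 19 progenitor and cell cycle genes, 4 rose and 3 fell: Tyms rose by 0.93 ± 0.18 and Cdk1 by 0.95 ± 0.23, Gli2 fell by 0.53 ± 0.10, and Birc5 had 39 reads in cKO and 16 in WT without passing limma.

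Of 30 muscle genes, 7 rose and 1 fell. Casq1, the calsequestrin gene of skeletal muscle, rose by 4.95 ± 0.11, from 57 reads over the WT libraries to 1946 over the cKO libraries. The skeletal actin gene Acta1 rose 5.50-fold and Mylpf by 1.32 ± 0.29. Tnnc2 had no reads in WT and 12 over the 4 cKO libraries, at least 4.09-fold higher, counting 3 reads over the group for the floor. Of 22 presynaptic genes 9 rose and 4 fell, with Stx1a and Syn3 2.82-fold and 2.72-fold higher, Cplx1 1.45-fold and Vamp1 1.37-fold. Of 28 potassium channel genes 10 rose and 6 fell. Kcnq3 rose by 0.65 ± 0.07 and Kcna3 by 0.60 ± 0.10, and Kcnb2 differed by 0.71 ± 0.23.

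Of 17 ionotropic glutamate receptor genes, 6 fell and 1 rose: Grin2b rose by 0.29 ± 0.08, and Grin2c and Grik3 differed by -0.34 ± 0.10 and -0.25 ± 0.07. Of 15 GABA-A receptor genes, 3 rose and 1 fell, with Gabra6 up by 0.20 ± 0.05. Gabrq differed by 1.32 ± 0.42. Among 18 heat shock genes 7 fell and 1 rose. Hspb8 rose 3.27-fold, and Sdf2l1, Pdia4 and Hspa5, chaperones of the endoplasmic reticulum, differed by -0.49, -0.45 and -0.28. Among 16 clock genes 8 rose and 2 fell: Nr1d1 rose by 0.41 ± 0.10 and Ciart by 0.38 ± 0.08, and Npas2 and Cry1 fell by 0.50 ± 0.13 and 0.39 ± 0.09.

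Among 16 genes of the histone variant H2A.Z and its exchange machinery, 2 rose and 3 fell. The H2A.Z chaperone gene Anp32e fell by 0.38 ± 0.07 and Vps72 by 0.26 ± 0.07, Yeats4 rose by 0.26 ± 0.06, and H2afv differed by 0.22 ± 0.07. Of 17 glucocorticoid-responsive genes 1 was higher and 3 were lower, none past limma: Map3k6, Zbtb16, Mt1 and Mt2 differed by 0.76, -0.31, -0.25 and -0.21. Of 29 Hox genes 3 were listed, all at few reads. Hoxb4 had no reads in cKO and 11 in WT, at least 3.59-fold lower with 3 reads over the group for the floor. Hoxb5 had 5 reads in cKO and 22 in WT, and Hoxb8 had 18 and 4. Both directions turned in part of the libraries: Hoxb5 differed by 0.21 without WT replicate 1, and Hoxb8 by -0.48 within libraries 3 and 4.

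Limma, adjusted over all features tested, passed 2214 higher and 1365 lower genes of the cKO table. Groups did not overlap in 78.0% of its genes, where chance gives 2.86%. That share describes genes chosen for differing.

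**Figure D2:**
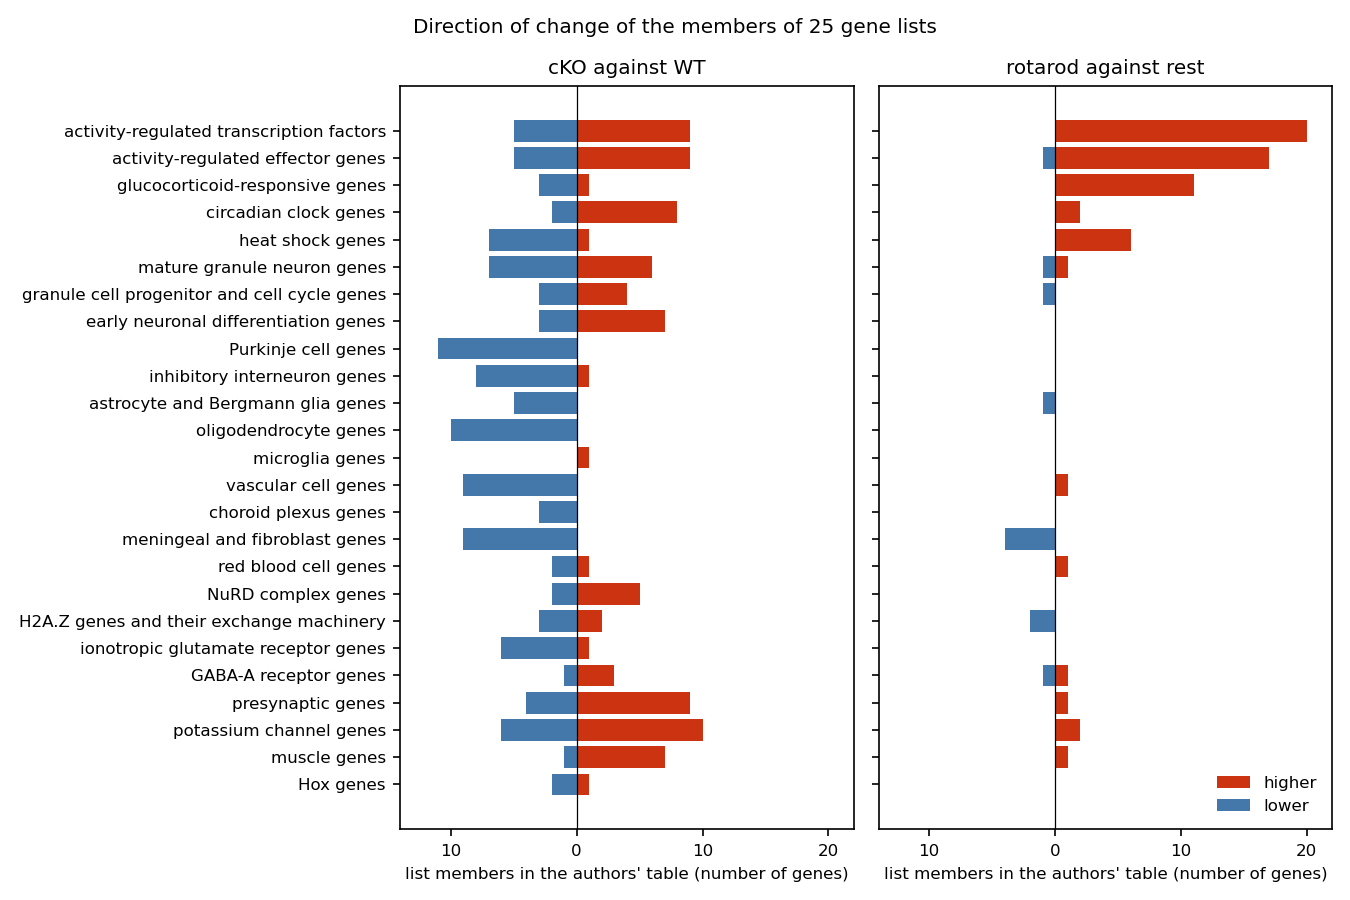
Number of members of each of 25 gene lists that the authors' deposited tables list as higher (right of 0) or lower (left of 0), for cKO against WT and rotarod against rest. In cKO the Purkinje, oligodendrocyte, vascular and meningeal lists extend to the left alone, and after rotarod training the activity-regulated lists extend to the right.

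Rotarod training was compared with rest to find the genes that motor activity changes in the cerebellum. The authors' deposited table lists 908 genes, 555 higher and 353 lower after training. Activity-regulated transcription factor genes rose together: 20 of 24 rose and none fell, 13 of them also past limma (Fisher's exact test against the other listed genes, adjusted p = 0.00115). Fos rose 16.4-fold, from 2.62 ± 0.41 to 6.65 ± 0.29 log2 CPM (SD, n = 4), and Fosb 21.4-fold. Nr4a3 rose 8.69-fold, Npas4 7.56-fold, Nr4a2 6.94-fold, Nr4a1 5.32-fold and Fosl2 4.34-fold (limma adjusted p of at most 0.0102).

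Of 33 activity-regulated effector genes, 17 rose, 10 of them also past limma, and 1 fell (Fisher's exact test, adjusted p = 0.0196). Dusp1 rose 4.48-fold, Cyr61 3.44-fold, Spry4 2.52-fold and the clock gene Per1 2.29-fold. The member that was lower was Arc, at -0.57 ± 0.20. It was named after its value was seen. Of 17 glucocorticoid-responsive genes 11 rose, 2 of them also past limma, and none fell (Fisher's exact test, adjusted p = 0.0469): the kinase gene Sgk1 rose 2.11-fold, and Zbtb16, Hif3a and Map3k6 differed by 1.39 ± 0.44, 1.13 ± 0.32 and 0.86 ± 0.36. Of 18 heat shock genes 6 rose and none fell, with Fisher's exact adjusted p of 0.279. Among genes at or above the median abundance, where 7 transcription factor, 6 effector and 6 glucocorticoid genes rose and none fell, the unadjusted Fisher's exact p of these 3 lists was 0.11, 0.186 and 0.186. Hspa1a rose 2.88-fold, Dnajb1 1.85-fold and Hsph1 1.75-fold, and Hspa1b differed by 1.74 ± 0.32. Hspa1a and Hspa1b are near-identical copies, and how reads were divided between them is uncertain.

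Eomes, a gene of unipolar brush cells, rose 2.49-fold and the antiproliferative gene Tob2 2.45-fold. Egr4 differed by 1.24 ± 0.21 and the peptide transporter gene Slc15a2 by 1.48 ± 0.53, neither past limma. Slc15a2 was 6.65 in rotarod library 3 and 5.11 to 5.26 in the other 3. Among abundant genes the lowest was Cirbp, a cold-inducible RNA-binding protein gene, 1.83-fold lower (limma adjusted p = 0.00612). Zbtb18 was 1.62-fold lower, Angel1 1.48-fold, Guf1 1.45-fold, the transferrin receptor gene Tfrc 1.44-fold and the noncoding RNA Neat1 1.44-fold. Zc3h6, Aebp1, Cep83os, Flrt3, Slc13a4 and H3f3b had log2 differences of -0.62, -0.62, -0.51, -0.55, -0.55 and -0.53 and did not pass limma. H3f3b has processed copies in the genome, so its value is uncertain.

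Few cell type markers were listed after training, and few genes of any kind were (3.38% of the features tested). Of 13 meningeal and fibroblast genes 4 were listed, all lower: Slc6a13, Slc22a6, Fmod and Col1a1 differed by -0.65, -0.52, -0.46 and -0.44. The astrocyte gene Sox9 differed by -0.43. The vascular gene Flt1 was higher by 0.38 and the blood gene Hba-a1 by 0.67. Other listed members were Cry1 (0.41), Tiam1 (0.32), Cbln1 (-0.42), Ccnd1 (-0.34), Dmap1 (-0.45), Kat5 (-0.29), Gabrq (-1.06), Gabra2 (0.69), Bsn (0.45), Kcna5 (1.55), Kcnk1 (0.30) and Ryr1 (0.24), as log2 differences that did not pass limma. No member of the Purkinje, interneuron, oligodendrocyte, microglia, choroid plexus, NuRD, early differentiation, glutamate receptor or Hox lists appears in this table, and neither does Chd4. Limma passed 113 higher and 54 lower genes of the table. Leaving out any 1 of the 8 libraries lowered these counts to between 44 and 67 higher and between 10 and 19 lower.

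Genes changed by training were then looked up in the cKO table, since the series title links chromatin remodeling with activity genes. The 2 comparisons use separate libraries. Of the genes in both tables (322), 75 rose in both, 50 fell in both, 132 rose with training and fell in cKO, and 65 fell with training and rose in cKO. Independent lists would share 61.7, 33.0, 52.0 and 39.2 genes in these classes. These expected counts take every feature tested as equally likely to be listed and were not matched on abundance. Every class held more genes than expected, so the excess alone shows no link between training and genotype. Among the shared genes direction was opposite more often than not (odds ratio 0.437, Fisher's exact test p = 6.37e-04). Genes are not independent replicates. The 22 shared genes of the activity-regulated lists were mixed: 13 rose in both, 8 rose with training and fell in cKO, and Arc did the reverse, 0.57 ± 0.20 lower with training and 1.47 ± 0.12 higher in cKO. Fos, Dusp1, Fosl2 and Cebpb were higher in both, with cKO differences of 1.11 ± 0.36, 0.76 ± 0.09, 0.46 ± 0.17 and 0.90 ± 0.12. Nr4a3, Nr4a1, Egr4, Dusp4 and Klf2 were higher with training and lower in cKO. Their cKO differences were -0.62 ± 0.28, -0.24 ± 0.08, -0.64 ± 0.13, -0.71 ± 0.07 and -0.33 ± 0.17. Across both genotypes, Nr4a3 also differed by 0.77 between libraries 1 and 2 and libraries 3 and 4. These genes were named after their values were seen. Between genes that passed limma in both tables, 30 in all, the odds ratio was 0.818 (Fisher's exact test p = 1).

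**Figure D3:**
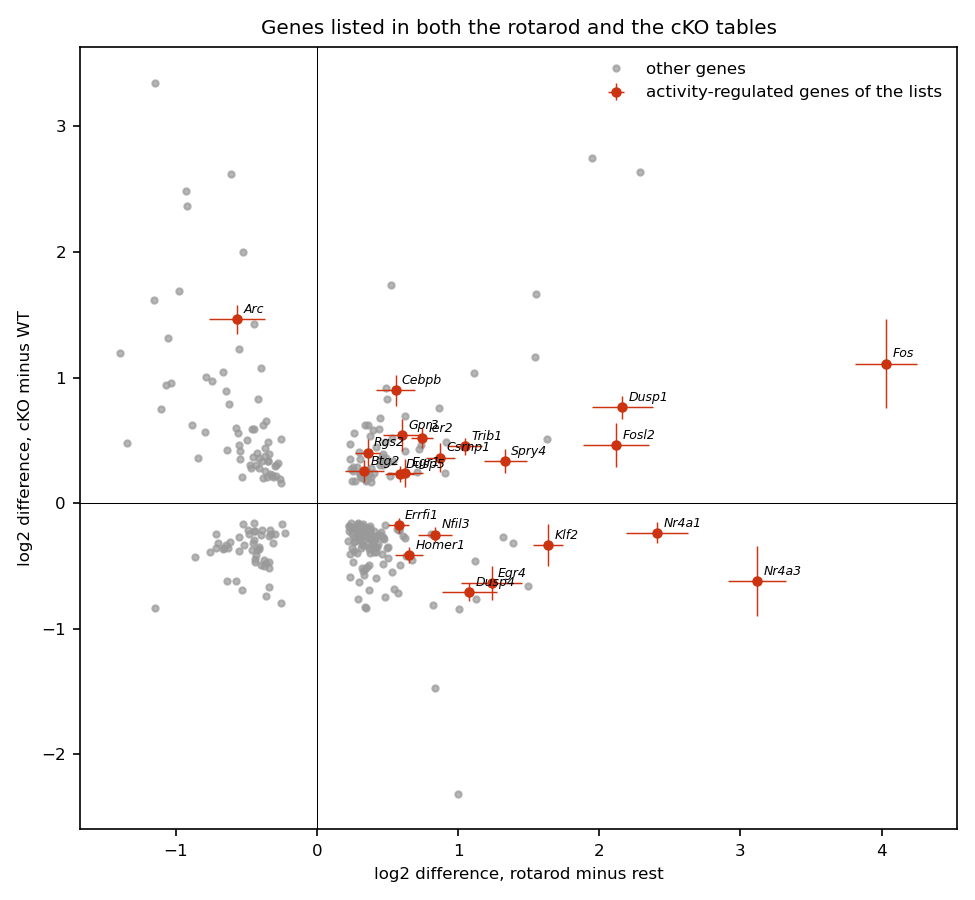
Log2 difference with rotarod training (horizontal axis) and in cKO (vertical axis) of the genes that both of the authors' deposited tables list. Each point is a gene, red points are members of the activity-regulated lists with bars of 1 SE, and Fos lies farthest to the right.

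Sync-TRAP compared ribosome-bound RNA of cKO and WT cells at postnatal day 12, 6 days after electroporation. The authors' deposited table lists 38 genes, 30 higher and 8 lower in cKO. Most of the higher genes had almost no reads in the WT IP libraries. Npas4, an activity-regulated transcription factor gene, had 2 reads over the 3 WT libraries and 499 over the 3 cKO libraries, a ratio of 278 (95% exact binomial interval 76.4 to 2298, counting error only). IP cKO replicate 3 held 364 of the 499 reads, and without it the ratio was 114. The genes Gatsl3, Gal (the galanin gene), Emilin3, Lhfpl5, Wnt9a, Nupr1, Cpne7 and Il34 had no reads in WT. They were at least 260-fold, 139-fold, 110-fold, 107-fold, 92.7-fold, 65.3-fold, 60.1-fold and 42.3-fold higher in cKO, with 3 reads over the group for the floor. IP cKO replicate 3 held the highest of the 3 cKO values for 19 of the 30 higher genes. In 11 of the 17 with at most 3 WT reads, the limit or ratio was lowest without it, and in the others without replicate 1 (4 genes) or 2 (2 genes). The lowest limits with 1 cKO library left out, in the same order, were 11.3-fold, 25.3-fold, 42.8-fold, 10.7-fold, 63.1-fold, 49.1-fold, 28.4-fold and 33.8-fold. With 1 or 2 reads in WT, Crabp1 and Kank4os had ratios of 1494 (413 to 12342) and 524 (93.6 to 20738). Gstm6 had a ratio of 360 (64.2 to 14279), Abcc3 363 (64.6 to 14367) and Tnfrsf1b 299 (53.3 to 11863), by the same interval. Crabp1 had nearly all of its reads in 1 cKO library, with 6.79 log2 CPM in IP cKO replicate 3 and -2.27 and -3.71 in the other 2. Without a single cKO library, the lowest ratios of Crabp1, Kank4os, Gstm6, Abcc3 and Tnfrsf1b were 2.53, 329, 260, 77.7 and 201. Cd180 differed by 6.21 ± 1.02.

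Among the lower genes, Krt26 and Aass had no reads in cKO and were at least 134-fold and 133-fold lower. The reads of Krt26 lay in 2 of the 3 WT libraries, and 413 of the 445 reads of Aass in IP WT replicate 3. Without the WT library of most reads the limits were 40.0-fold for Krt26 and 14.6-fold for Aass. Pecr had 1 read in cKO and 330 in WT, 240 of them in IP WT replicate 3, and Pou2af1 had 37 and 1580. The calcium channel gene Itpr1, a Purkinje marker, differed by -1.23 ± 0.73. The Y-linked genes Ddx3y, Uty and Kdm5d had 710, 788 and 1381 reads in IP WT replicate 1 and at most 2 in any other IP library. Limma passed none of the 38 genes after adjustment, and 31 had an unadjusted p under 0.05. Chd4 is not in this table.

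Of these 38 genes, 17 (44.7%) also appear in the table of cKO and WT cerebellum at days 27 to 28, which lists 20.3% of the features tested. Direction was the same for 15 of them. Among the higher genes, 14 of 30 also rose at days 27 to 28, where 11.03% of features rose (exact binomial test, p = 1.02e-06). Genes are not independent replicates, and this share of features was not matched on abundance. They included Cpne7, Wnt9a, Abcc3 and Nupr1, with later log2 differences of 6.33 ± 0.26, 2.36 ± 0.10, 2.25 ± 0.14 and 1.34 ± 0.13. With 0 or 1 WT read at day 12, their sizes at the 2 ages cannot be compared. Itpr1 was lower in both, and Gmeb2 and Krt26 went opposite ways. Genes shared with other tables were named after their values were seen.

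The pull-down was compared with its input in WT to see which RNAs it enriched. The authors' deposited table lists 30 genes higher and 21 lower in IP. The differences ± SE below come from limma without a block, as the fixed design set, and so leave out the pairing of pull-down and input. Calls with the block are given after those without it. Higher were Atg7, an autophagy gene (3.83 ± 0.72), Ubr3 (2.87 ± 0.40), the histone demethylase gene Kdm6b (2.64 ± 0.74), Gse1 (2.06 ± 0.69), Arid1b (1.97 ± 0.44), the splicing factor gene Sf3b1 (1.88 ± 0.54), Tnrc18 (1.88 ± 0.51), Ddx46 (1.57 ± 0.54), Supt6 (1.55 ± 0.39), Arglu1 (1.51 ± 0.80), the granule neuron receptor gene Grm4 (1.42 ± 0.45) and Neurl1b (1.31 ± 0.37). The vesicular glutamate transporter gene Slc17a7, was higher by 1.19 ± 0.32, the only one listed of 22 mature granule neuron genes. Among the lower genes were noncoding RNAs that did not pass limma without a block, with differences of -3.81 ± 0.43 for the nuclear RNA Rn7sk, -2.84 ± 0.48 for Rpph1, and -2.87 ± 0.61 and -2.52 ± 0.58 for the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1. Hopx, the only one listed of 16 astrocyte and Bergmann glia genes, differed by -2.23 ± 0.44, and the glial apolipoprotein gene Apoc1 is listed at 0 reads in IP. Other lower genes under the naming rule, all protein-coding, were Cstad, Crabp1, Gatsl3, Nupr1, Wnt9a, Cd180 and Apmap. Of these, Cstad, Gatsl3, Nupr1 and Wnt9a are also listed at 0 in IP. Outside that rule, the noncoding RNAs Malat1 and Gm23624 differed by -2.27 ± 0.48 and -3.73 ± 0.78. The mitochondrial genes mt-Co1, mt-Cytb and mt-Nd5 differed by -2.05, -2.03 and -1.54, and Snhg11, Fam21 and Sltm were lower too. Limma passed 3 genes after adjustment, Nupr1, Cd180 and Apoc1, all lower, and 50 of the 51 had an unadjusted p under 0.05. For Nupr1 and Apoc1 the IP libraries had no spread, at 0 reads in each. With the replicate number as a block limma passed 6 lower genes, these 3 and Crabp1, Cstad and Rn7sk (adjusted p under 0.05). Without the block, the 3 calls ended (0 lower genes) when any library but IP WT replicate 2 was left out, and with pseudocounts of 1 or 5 CPM, and without IP WT replicate 2 limma passed 2 higher and 9 lower genes. Chd4 is not in this table.

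The 2 Sync-TRAP tables share the IP WT libraries. They have 6 genes in common, Cd180, Wnt9a, Gatsl3, Nupr1, Crabp1 and Apmap, each lower in IP WT than in input and higher in IP cKO than in IP WT. In 100 simulations of unchanged groups against the same libraries, lists of these lengths shared 2.11 genes on average and 5 at most, all in opposite directions. The simulated values were normal, with equal spread and no floor, while Wnt9a, Gatsl3 and Nupr1 had no reads in any IP WT library. The simulated counts therefore show the direction that shared libraries give, and set no limit for the 6 genes. Independent lists would share 0.0332 genes of opposite direction. Part of the excess may come from the shared libraries, and 3 libraries were too few to split.

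Region lists at day 22 gave 15127 start site regions with the histone mark H3K4me3 and 26183 enhancer regions with H3K27ac, each 1000 bp wide on build mm9. No enhancer region overlapped a start site region by 1 bp or more. The median gap from an enhancer to the nearest start site region was 49.8 kb (quartiles 19.7 and 120.1 kb), and the smallest was 452 bp. Of the enhancers, 12.5% lay within 10 kb of a start site region and 70.4% within 100 kb. The X chromosome held 541 start site regions and 377 enhancers, and the Y chromosome 4 and 0. The lists give no values per sample and no gene names.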

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

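The tests in this part of Sync-TRAP genes, of Y-linked genes, of the 6 marker lists and of other splits were chosen after the results were seen.

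In single libraries, 24 of 342 groups of 4 libraries of named genes held a library far from the other 3. Chance flags about 1 in 20 groups, or 17 here. In the cKO comparison these values, in log2 CPM, were Elavl2 5.005 (others up to 4.80), Svep1 5.89, Stx1a 2.43 and Hoxb5 0.55 in WT replicate 1, Hspa5 8.71 in WT replicate 2 and Yeats4 4.26 in WT replicate 4. They were also Chd4 8.06 (others 7.90), Dusp4 2.31, Cdh5 4.002 and H2afv 5.10 in cKO replicate 1, Miat 6.73 in cKO replicate 2, Grik3 6.52 in cKO replicate 3, and Itpr1 11.95 and Prkcd 7.19 in cKO replicate 4. In the rotarod comparison they were Fos 3.23, Cep83os 4.28 and Fosb -1.52 in rest library 5, Zc3h6 4.67 in rest library 2, and Sgk1 6.31 and Gabrq -0.37 in rest library 6. Slc15a2 6.65 in rotarod library 3, H3f3b 6.75 in rotarod library 4, and Npas4 5.08 and Ryr1 6.66 in rotarod library 8 were the others.

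Between ages, Gmeb2 was higher in the cKO pull-down at day 12 (2.30 ± 0.80) and lower in cKO cerebellum at days 27 to 28 (-0.37 ± 0.06), and Krt26 was lower at day 12 and higher later (1.19 ± 0.24). Krt26 had no reads in the cKO pull-down, so its fitted day 12 difference of -4.35 is set by the prior count. It was at least 134-fold lower, with 3 reads over the group for the floor, and at least 40.0-fold without IP WT replicate 1. The differences between ages were not tested, tissue and assay differ too, and Krt26 had reads in 2 of the 3 WT pull-down libraries.

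Markers of 9 other cell types were lower in cKO for 57 of 60 listed genes. A scaling offset between genotypes would lower abundant genes too. Of the 1377 most abundant listed genes (mean log2 abundance of 6.21 or more), 47.6% were higher in cKO (exact binomial interval 44.9 to 50.2), with a median log2 difference of -0.15 beside -0.28 for the markers. The scaling of the libraries sets this balance and only called genes enter it, so it leaves an offset open. A lower share of RNA from all other cell types predicts like falls, yet mean changes differed over 8 lists (permutation p = 0.00213). Without choroid plexus and red blood cell genes the other 6 lists had means of -0.35 to -0.22 (permutation p = 0.213). For those 6 lists a lower share of their RNA, or an offset, may account for the falls, and these cannot be told apart from lower expression in each type, because only called markers have values.

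Of the 30 RNAs higher in the cKO pull-down at day 12, 21 had at most 8 reads over the WT pull-down libraries and the other 9 had 107 to 1794. Loss of rare RNAs from the 3 WT libraries would leave the first 21 with few reads, and would leave them in the WT input at about their level in the cKO pull-down, and for the 5 of them with an input value the mean difference was -0.57 log2 (range -1.17 to 0.36; -0.49 over 6 genes with Apmap, which had 107 WT reads). Those genes had to be higher in the input to be listed, and the other 16 have no input value, so for the 21 this loss cannot be told apart from a genotype effect. A genotype effect predicts that the genes also rise later, and 14 of 30 did (exact binomial test, p = 1.02e-06), 10 of the 21 and 4 of the 9. That test takes genes called from the same libraries as independent, against a share of all features not matched on abundance. Its p therefore does not measure the spread between samples. Both explanations may hold for the 21.

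The Y-linked genes Ddx3y, Uty and Kdm5d were over 10 reads in 1 of 6 pull-down libraries. One WT library with tissue from a male, and no other such library, predicts this and may be the source of these 3 calls. Without that library Ddx3y and Uty differed by 0.14 and 0.14 in the other direction. No biological explanation by genotype was tested.

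For other splits of the libraries, limma passed 3579 genes of the cKO table under the real split and at most 0 under any of the other splits (1 of 35 gave as many). For the rotarod table it passed 167 and at most 2 (1 of 35). The genes were listed for differing under the real split, so these counts do not exclude chance. With 3 libraries per group there are 10 splits, too few for a share under 0.05. For IP cKO against IP WT the real count was 0 and the highest other 0 (10 of 10 splits gave as many), and for IP against input 3 and 0 (1 of 10).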

How the results depend on the processing

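Limma-trend, pseudocounts of 1, subsets of libraries, all limma alternatives for Sync-TRAP adjustment and pseudocounts, the Y-linked exclusion, the block of rotarod columns, the Sync-TRAP fold limits with a library left out, the test of genes with at most 10 WT reads, the 2-fold and limma forms of the rotarod overlap, and the Fisher tests of direction were added after the data were seen. A threshold of 0.1 was not run because genes past 0.05 are not listed, and count models and unfiltered tests were not run without counts. Among the authors' calls (higher and lower), a log2 fold of at least 1 left 868 and 170 in cKO and 112 and 47 in rotarod, and 0.5 left 1556 and 598, and 252 and 154. The median abundance left 1336 and 1418, and 319 and 135. Bonferroni over the table left 1470 and 808, and 283 and 115. An adjusted p under 0.01 left 357 and 161 in rotarod, 2 and 1 in IP cKO against IP WT, and 15 higher in IP against input. Without the Y-linked genes, 5 lower genes were left in IP cKO. These are smaller by construction.

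Limma counts in cKO fell from 2214 and 1365 to 460 and 102 with Bonferroni over the table, 454 and 95 in libraries 1 and 2, and 842 and 247 in libraries 3 and 4, and adjustment over the table gave 2329 lower. In rotarod, 113 and 54 became 195 and 91 with a trend, 550 and 346 adjusted over the table, 51 and 13 with Bonferroni, 83 lower with a pseudocount of 1, 176 and 94 with 5, and 0 and 0 in each subset of 4 libraries. With 1 library left out, the counts were 1714 to 1965 higher and 915 to 1085 lower in cKO, and 44 to 67 and 10 to 19 in rotarod. In IP cKO against IP WT, 0 and 0 became 27 and 3 adjusted over the table and 8 and 1 with Bonferroni, and stayed 0 with 1 library left out. In IP against input, 0 and 3 became 29 and 21 adjusted over the table and 2 and 11 with Bonferroni, 6 lower with a trend and 0 lower with pseudocounts of 1 and 5. Leaving out 1 library gave 0 to 2 higher and 0 to 9 lower, the highest without IP WT replicate 2. The changed adjustments differ in the number of tests and the subsets in the number of libraries, and no other cause was tested.

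The odds ratio of the rotarod and cKO directions, 0.437, was 0 for the 100 smallest p per direction (2 shared genes, Fisher's exact test p = 1), 0.818 for limma calls and 0.156 for rotarod changes of at least 1 (p = 0.113), and it passed the test at 0.01 and above the median abundance. Single genes that changed sign were Hoxb8 in libraries 3 and 4 (-0.48), Hoxb5 without WT replicate 1 (0.21; range with 1 library left out -0.93 to 0.21), and Uty and Ddx3y without IP WT replicate 1 (0.14 and 0.14, ranges from -4.19 and -4.12). Of the named genes, 22 in cKO, 10 in rotarod, 2 in IP cKO (Uty and Ddx3y) and 3 in IP against input lost limma's call, or changed sign, with some library left out. Same-numbered cKO and WT libraries correlated at 0.098, 0.16, 0.13 and 0.085 in their deviations, cKO 4 correlated best with WT 3, and the numbers were taken as not pairing. For the pull-downs the correlations were 0.185, -0.0771 and 0.221 between genotypes. With the number as a block, limma passed 1811 and 1037 genes in cKO, 0 and 0 in IP cKO, and 0 and 6 in IP against input, where it changed no call of a named gene but those of Crabp1, Cstad and Rn7sk. In cKO the block lowered the counts from 2214 and 1365. Yet the named genes that passed only with it included Fos, Kcnb2 and Sdf2l1 (limma adjusted p = 0.0136, 0.00577 and 0.038). No paired analysis was possible because, for rotarod, each column number belongs to 1 library and to no sample title. With columns 1 to 4 and 5 to 8 as a block, limma passed 107 and 53 genes there, and no named gene gained or lost its call. Among abundant genes, the unadjusted Fisher's exact p of direction in cKO was 0.001 for Purkinje, 0.00793 for oligodendrocyte, 0.0315 for meningeal and 0.5 for vascular genes. In rotarod it was 0.11 for activity-regulated transcription factors and 0.186 for the effector and glucocorticoid lists. Enhancer overlap at 50% of a region had to be 0, as no enhancer overlapped by 1 bp, so that setting tests nothing further. Merging left 12685 start site and 26171 enhancer regions. Counting limits genes of few reads, such as Tnnc2, the Hox genes and most Sync-TRAP genes.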

Other observations

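The symbol families, Rbm3 and the test of warmer tissue were looked at after the data were seen. Among listed genes in cKO cerebellum, 16 of 16 with Rpl symbols were higher (median log2 difference 0.41), 16 of 18 with Rps symbols were higher (0.36), and 13 of 13 with Pcdhb symbols, clustered protocadherin genes, were lower (-0.43). Among 46 symbol families with at least 10 listed genes in cKO, these had a direction apart from that of other listed genes (Fisher's exact test, adjusted p = 0.00129 for Rpl and Pcdhb and 0.0259 for Rps). The Rps symbols include 3 kinase genes, and both ribosomal families include pseudogenes. Of 51 Rpl and 32 Rps protein genes in the reference, 15 and 13 are listed, all higher (medians 0.39 and 0.34, Fisher's exact test, p = 1.11e-04 and 3.88e-04), and 36 and 19 are not listed and have no value. Of 22 Pcdhb genes 9 are not listed. For rotarod, 4 families were tested, and Slc (6 higher, 14 lower) and Tmem (4 and 11) also passed (adjusted p = 0.0132 for each). Their members share a name rather than a function. Ribosomal protein genes have many processed copies and Pcdhb genes resemble one another, so their values are uncertain.

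Chaperone genes rose after rotarod training and Cirbp, which cold induces, fell by 0.87 ± 0.09. A candidate explanation is warmer tissue in the trained mice. All 6 listed heat shock genes were higher, but so were most listed genes, and the test missed the threshold (Fisher's exact test, p = 0.0871). Rbm3, the other well-known cold-induced RNA-binding protein gene, went the opposite way from Cirbp, up by 0.74 ± 0.06 (limma adjusted p = 0.0032). It was not part of the prediction, and a single gene picked after the data were seen cannot decide the question. The hypothesis stays open, with 1 cold-induced gene on each side.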
